A study of Mus musculus with 3 samples.

How the data were processed

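Cells of the mouse medial prefrontal cortex were profiled by droplet single-cell RNA sequencing in 3 libraries: 1 from 2 females in estrus, 1 from 2 females in diestrus and 1 from 2 males. Per the labels' protocols, tissue was digested with papain, debris was removed on Percoll, 15000 cells were loaded per library with the 10x Genomics 3′ kit, and the libraries were sequenced on an Illumina instrument. No sort for neurons is described, and the labels' term for neurons was not taken as a filter: cells of every type were analysed. The 2 mice of a group were pooled in 1 library and cannot be separated in these data.

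The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the submitters' processing notes they were made with Cell Ranger 3.0.2 on the mm10 genome, while per the file headers the software was Cell Ranger 7.0.0. The gene annotation used by the authors, whether intronic reads were counted, whether counting used strand and how cells were called are not given in the sources used here. Every barcode in the matrices held at least 500 UMIs. The same 32285 genes were listed in each library, and 32235 matched the GENCODE annotation of mm10 by gene identifier, which gave the coordinates and gene lengths printed here.

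Matrices held 14476 barcodes in the estrus library, 18052 in the diestrus library and 19555 in the male library, with 152291602, 144738154 and 115632520 UMIs. Barcodes with fewer than 500 detected genes (970, 1986 and 2111) or with more than 15% of UMIs from mitochondrially encoded genes (653, 1321 and 1293) were removed. Doublets were scored with Scrublet (in scanpy 1.11.5) per library. Its automatic limit called 788 barcodes in estrus, 607 in diestrus and 0 in male, so it had not worked in the male library, and a common limit of 0.3 was set after the scores were seen; 709, 745 and 892 barcodes lay above it. After all filters, 12289, 14146 and 15493 cells were retained, with a median of 6136, 4681.5 and 3900 UMIs per cell.

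Retained cells of the 3 libraries were log-normalised and clustered together with the Leiden algorithm (igraph 0.11.9) at resolution 1, on 2000 variable genes, 30 principal components and 15 neighbours, without batch integration. Xist, Tsix, Y-linked, mitochondrial, ribosomal protein, haemoglobin, immediate early and heat shock genes were kept out of the variable genes. Clusters were named from marker sets fixed in advance, with at least 3 markers detected. Several naming settings were set after the clusters were seen: markers counted as detected from 20 CPM (counts per 1000000), erythroid clusters needed 50% of UMIs from haemoglobin genes, and clusters with a median doublet score above 0.2 or a class score below 0.5 stayed unnamed. Clusters with more markers of another class than of their own among their 10 leading genes, or of low UMI count without a marker there, also stayed unnamed. The limit for low UMI count was stricter here than in the alternative that left out low-UMI neuron sub-clusters. That alternative took a median UMI ratio to the library below 0.5, so named sub-clusters are among those it left out. Unnamed low-UMI clusters held 2.91% of estrus, 21.2% of diestrus and 16.7% of male cells, and clusters led by another class's markers held 0.578%, 0.912% and 2.59%. Clusters of high doublet score held 0.407%, 0.509% and 1.00%. Neurons were clustered again in the same way into subclasses. Neuron sub-clusters with 2 or more markers of another class among their 10 leading genes were removed, a step also added after the clusters were seen; they held 1.86%, 2.26% and 5.39% of cells, and a version with them kept is among the alternatives.

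With 1 library per group there was no replicate check, no test was run, and no p-value, standard error or count of altered genes was made from cells. Raw counts were summed per library and class, divided by the class total over nuclear genes and multiplied by 1000000 (CPM). Log2 ratios of 2 libraries carry 1 CPM added to each side. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals of the ratio without the added CPM, so they can lie to one side of a low gene's printed value. UMI sums carry exact Poisson intervals and shares of cells Clopper-Pearson intervals, and a count of 0 was given the limit that 3 counts allow. All intervals cover counting error only. A ratio compares these libraries, not the conditions. The classes compared had at least 100 retained cells in every library.

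The genes named in the text were taken by a rule of size fixed before the data were examined, as were the gene lists, the cell type markers, the 3 comparisons and all alternatives not marked below as added. Candidates had at least 100 UMIs over the 2 libraries and a mean of at least 20 CPM. The 10 highest and 10 lowest log2 ratios were taken per pair in glutamatergic neurons, and the 5 and 5 in GABAergic neurons and in the most numerous class that is not neuronal, which was microglia. In glutamatergic neurons, the 5 and 5 genes furthest from both other libraries, by the smaller of the 2 ratios, were also taken for estrus and for male, with the mean of at least 20 CPM taken over the 3 libraries. Sex check genes, mitochondrially encoded, ribosomal protein and haemoglobin genes, unnamed gene models, and genes at least 10 times higher in another class were left out of the naming. In glutamatergic neurons, estrus against diestrus, 331 of 7342 candidates were left out by category and 306 for another class, leaving 6705. For estrus against male, 343 and 305 of 7413 were left out, and for diestrus against male 355 and 307 of 7373. In GABAergic neurons 6778, 6843 and 6846 genes remained in the 3 pairs, and in microglia 6202, 6244 and 6265.

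There were 27 lists: sex chromosome check genes, steroid receptors and steroid metabolism, estrogen responsive genes, neuropeptides, peptide and hormone receptors, calcium channels, potassium and HCN channels, sodium channels, glutamate receptors, GABA receptors, monoamine and acetylcholine receptors, synapse scaffolds, immediate early genes, late activity genes, heat shock genes, glucocorticoid responsive genes, clock genes, cholesterol synthesis, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, interferon response, microglial homeostatic genes, microglial activation genes, astrocyte reactive genes, myelin genes, and endothelial barrier and transport genes. Some genes stand in more than 1 list. A list's value is the median log2 ratio of its members with a mean of at least 5 CPM, given where at least 3 were measured. It stands beside its percentile among 10000 random lists of the same size matched on mean expression (drawn within 50 ranks on each side, seed 7). The percentile describes these libraries and is not a p-value.

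Cacna1h was fixed in advance as a gene of interest. Its share of cells with a UMI was taken after each cell was thinned to 2000 UMIs, leaving out shallower cells, and the share in microglia served as background. Alternatives covered the gene minimum, the mitochondrial maximum, doublets, the clustering, edgeR TMM factors (edgeR 4.0.16), the DESeq2 median of ratios factors (DESeq2 1.42.0), per-cell weighting, thinning, subclass weighting, the CPM added and the CPM filter on list members. Alternatives chosen after seeing the data were mixed neuron sub-clusters kept, low-UMI neuron sub-clusters left out, clusters of a class weighted alike, and ratios corrected for gene length. Weighting subclasses or clusters alike used only those with at least 20 cells in every library. It left out neurons without a subclass and the L6b and Sncg subclasses. An alternative of a list median was read as moved when it left the order-statistic interval over the list's members, which is wide.

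The steps were tested on simulated counts drawn from the glutamatergic means and library totals, with known genes altered by a log2 ratio of 1. For estrus against diestrus, 193 of 7330 genes were altered; the median absolute error was 0.0244, and 95.4% of intervals held the simulated value. For estrus against male (189 of 7326 genes) the error was 0.0239 and the coverage 95.2%, and for diestrus against male (189 of 7335 genes) 0.0260 and 95.3%. All 20 named genes were among the altered ones in each comparison. Of 40 unaltered lists, 3, 0 and 0 lay outside the central 95% of random lists in the 3 comparisons. The simulated counts held Poisson counting noise only, with no variation between mice or libraries and no trend with gene length. They thus check the steps, not how firm the named genes or list percentiles are in these libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.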

Results

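The series asked how gene expression in cells of the medial prefrontal cortex (mPFC), a frontal cortical area tied to social and cognitive behaviour, differs with the estrous cycle and with sex. Droplet libraries were made from females in estrus, the stage of sexual receptivity, from females in diestrus, a stage of sexual non-receptivity, and from males, with 1 library and 2 pooled mice per group. Estrus against diestrus compared cycle stages, and each of them against male compared the sexes. The retained cells had medians of 6136 UMIs and 2588 detected genes in estrus, 4681.5 and 2255 in diestrus, and 3900 and 1998 in male. Glutamatergic neurons differed more in depth, with medians of 37392, 25439.5 and 10841 UMIs per cell. No difference below has a replicate check, every interval covers counting error only, and each ratio compares single libraries.

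The sex chromosome genes matched the labels of the 3 libraries. Xist, the RNA that silences an X chromosome in female cells (X: 103460366 to 103483254), reached 488 CPM (95% Poisson interval 484 to 492) in estrus and 615 CPM (610 to 619) in diestrus, against 10 UMIs (0.103 CPM) in male. The Y-linked translation factor gene Eif2s3y stood at 92.0 CPM and the Y-linked histone demethylase gene Kdm5d at 27.4 CPM in male. Both had 0 UMIs in the female libraries, which allows up to 0.0228 CPM in estrus and 0.0246 CPM in diestrus. Uty, another Y-linked demethylase gene, had 4, 3 and 6361 UMIs in estrus, diestrus and male. Ddx3y was at 1.42, 3.54 and 87.6 CPM, but its X-linked paralog Ddx3x can share reads with it, so its female values are uncertain. Tsix, antisense to Xist, was at 30.6 and 50.8 CPM in the female libraries, and counting by strand is not given in the sources used here. In glutamatergic neurons the list of sex chromosome check genes had a median log2 ratio of -0.31 for estrus over diestrus (0 of 6 measured members higher, percentile 0.880) and 0.26 for diestrus over male (percentile 100), while that for estrus over male turned from -0.06 to 0.06 with edgeR TMM factors.

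Most retained cells were not neurons, and the make-up differed between libraries. Microglia, the resident immune cells of the brain, made up 25.6% (Clopper-Pearson 95% interval 24.9 to 26.4) of estrus cells, 15.5% (14.9 to 16.1) of diestrus cells and 11.7% (11.2 to 12.2) of male cells. Endothelial cells followed the same order at 23.1%, 14.8% and 10.6%. Oligodendrocytes, the myelin-forming cells, were at 12.9%, 11.7% and 19.0%, and astrocytes at 11.3%, 7.37% and 12%. Glutamatergic neurons made up 11.1% (10.5 to 11.7), 12.3% (11.8 to 12.9) and 11.3% (10.8 to 11.8), and GABAergic neurons 1.43% (1.23 to 1.66), 2.15% (1.92 to 2.40) and 2.19% (1.97 to 2.44). Pericytes stood at 3.59%, 3.34% and 2.66%, oligodendrocyte precursor cells at 1.22%, 1.58% and 1.44%, and border macrophages at 0.895%, 1.03% and 0.671%. Cells left unnamed, mostly of low UMI count, made up 5.76% of estrus, 24.9% of diestrus and 25.7% of male cells, which lowers every other share in those libraries. Dissociation, the loading of 15000 cells and the depth of each library can also set these shares, and male microglia ranged up to 19.0% among the alternatives, with the order of the 3 libraries kept.

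**Figure D1:**
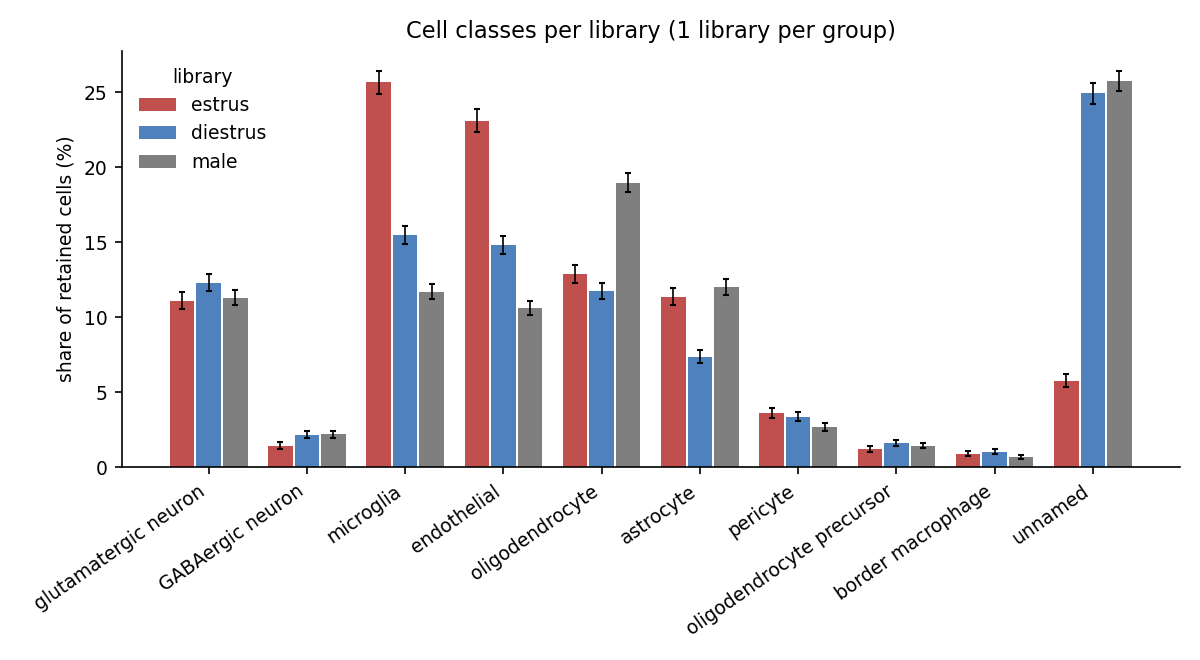
Share of retained cells (percent, vertical axis) in each named cell class and in unnamed clusters, with 1 bar per library (estrus, diestrus, male) and Clopper-Pearson 95% intervals that cover counting error only. Microglia stood at 25.6%, 15.5% and 11.7%, while unnamed cells stood at 5.76%, 24.9% and 25.7%.

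Among neurons, the diestrus library held relatively fewer upper layer and more deep layer cells. Neurons called L2/3 IT-like, which project within the cortex from the upper layers, made up 18.5% (16.6 to 20.6) of 1538 estrus neurons, 9.44% (8.21 to 10.8) of 2044 diestrus neurons and 18.0% (16.3 to 19.7) of 2088 male neurons. L4/5 IT-like neurons were at 16.1%, 11.4% and 15.9%. Of these, 65, 90 and 198 lay in glutamatergic subcluster 9, whose median UMI ratio to the library was 0.448 and which had no marker of that subclass among its 10 leading genes. L6 CT-like neurons, which project to the thalamus, were at 13.7% (12 to 15.5), 24.7% (22.8 to 26.6) and 20.7% (19.0 to 22.5), and L5/6 NP-like neurons at 4.94%, 10.8% and 6.90%. Subcluster 15 of L2/3 IT-like neurons held 35, 65 and 190 cells at a UMI ratio of 0.474. L6 CT-like subcluster 16 held 18, 108 and 179 cells at 0.386, and L5/6 NP-like subcluster 2 held 57, 166 and 112 at 0.419. L6 CT-like subcluster 20 (8, 94 and 57 cells) had no marker of its subclass among its 10 leading genes. Part of these shares thus lies in low-UMI neurons. L5 ET-like neurons, which project below the cortex, stood at 5.66%, 6.46% and 4.69%, and L6 IT-like neurons at 9.69%, 12% and 9.0%. No L6b-like neuron was found in estrus, which allows up to 0.195%, against 1.27% in diestrus and 1.05% in male. Interneurons called Sst-like stood at 3.90%, 3.91% and 5.84%, Vip-like at 1.5%, 2.50% and 2.63%, Pvalb-like at 1.43%, 1.81% and 2.44%, Lamp5-like at 2.08%, 2.84% and 1.77%, and Sncg-like at 1.24%, 1.91% and 1.92%. Neurons without a subclass made up 21.3%, 11.0% and 9.10%, which lowers the shares of the named subclasses in each library. Of these, 307, 164 and 155 lay in glutamatergic subcluster 6, which scored highest for L4/5 IT markers. At a clustering resolution of 0.5 the male L6 CT-like share was 13.2%, so the order of estrus and male in that subclass is not firm, whereas diestrus stayed highest. Glutamatergic subcluster 21, with 22 cells, held cells of the diestrus library only, as did the ependymal-like cells given below. Whether the tissue taken differed between libraries was not tested.

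In glutamatergic neurons the genes highest in estrus over diestrus had log2 ratios from 1.25 to 2.38. Cdkn1c, an inhibitor of cyclin-dependent kinases (7: 143458339 to 143461050), stood at 39.6 CPM in estrus and 8.35 in diestrus, a log2 ratio of 2.12 (95% interval 2.09 to 2.40). Wnt4, a secreted Wnt ligand (4: 137277489 to 137299726), was at 79.2 against 24.2 CPM, with a log2 ratio of 1.67 (1.62 to 1.81). With subclasses weighted alike these ratios were 1.11 and 1.21. The RNA-binding protein gene Hnrnpa0 (1.35, 1.30 to 1.42), the casein kinase 2 subunit gene Csnk2a2 (1.39), the protein phosphatase 2A subunit gene Ppp2cb (1.34) and Eid2 (1.25) kept ratios of 1.35, 1.28, 1.34 and 1.19 under that weighting. Tnnc1, a troponin gene, went from 1.29 to 0.16 with that weighting, and over male from 1.59 to 1.09. Cdkn1c, Tnnc1 and the PACAP gene Adcyap1 are among the 10 leading genes of unnamed glutamatergic subcluster 6, which held 307, 164 and 155 cells in estrus, diestrus and male. Having no subclass, these cells were left out of the weighting, so the smaller ratios can come from their removal. Gstp1 (2.08), a glutathione transferase gene, and Hist1h4d (1.62), a histone gene, have near-identical copies, so their values are uncertain. Cmss1 (16: 57302000 to 57606864) had the highest ratio at 2.38 (2.36 to 2.42). Cmss1, Hnrnpa0 and Gstp1 lay above 1 in 9 of 9 classes, so their ratios are not particular to these neurons.

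The genes lowest in estrus against diestrus had log2 ratios from -1.66 to -1.16. Grm3, a metabotropic glutamate receptor gene (5: 9485541 to 9725170), was at 148 CPM in estrus, 355 in diestrus and 387 in male, with a log2 ratio over diestrus of -1.25 (-1.30 to -1.22) and -1.21 with subclasses weighted alike. Glra2, the X-linked glycine receptor alpha 2 subunit gene (X: 165129017 to 165327393), was at 13.03, 43.3 and 39.7 CPM, a ratio over diestrus of -1.66 (-1.86 to -1.61), or -0.85 under that weighting. The serotonin receptor gene Htr1f (16: 64924729 to 65105854) had -1.25 (-1.31 to -1.21) and -0.73, the cadherin gene Cdh9 -1.31 and -1.0, and Tmtc1 -1.16 and -0.90. The ratios of Tle4 (-1.36), Foxp2 (-1.34), Nxph3 (-1.33), Thsd7b (-1.35) and Olfm3 (-1.19) shrank to -0.49, -0.44, -0.27, -0.51 and -0.39 once subclasses were weighted alike. Cdh9, Foxp2, Thsd7b and Olfm3 are among the 10 leading genes of a glutamatergic cluster or subcluster. Over diestrus, Nxph3 was lower by a log2 ratio of at least 1 in 8 classes, Htr1f and Foxp2 in 6, and Glra2 and Olfm3 in 5. Grm3 was so in 3 classes, and Tle4, Thsd7b, Cdh9 and Tmtc1 in 1. Those class counts had no CPM minimum, and free RNA in droplets can put neuronal UMIs into other classes. They thus cannot decide whether the lower ratios are particular to these neurons. Among genes with a mean of at least 20 CPM over the 3 libraries, estrus stood furthest from both others in Gstp1, Wnt4, Hist1h4d, Cmss1 and Hnrnpa0 among the higher genes, and in Glra2, Thsd7b, Nxph3, Tle4 and Foxp2 among the lower.

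By gene list, transmitter receptors were lower in estrus than in diestrus glutamatergic neurons, while late activity, heat shock and ribosomal protein genes were higher. Glutamate receptors had a median log2 ratio of -0.32, with 18 of 19 measured members lower (percentile 0.140). Examples were the kainate receptor gene Grik1, at 18.8 against 46.1 CPM, and the AMPA receptor gene Gria3, at 480 against 706. Monoamine and acetylcholine receptors had a median of -0.56, with 15 of 17 lower (percentile 0): Chrm3, a muscarinic receptor gene, was at 176 against 327 CPM and Htr2c, a serotonin receptor gene, at 27.7 against 50.5. Grik1 and Htr2c are leading genes of L5/6 NP-like glutamatergic subcluster 12, with 19 estrus and 55 diestrus cells. L5/6 NP-like neurons made up 4.94% of estrus and 10.8% of diestrus neurons, so these 2 genes can follow that share. GABA receptors had -0.26, with 10 of 13 lower (percentile 0.730) and Gabrb2 at 111 against 200 CPM. Many of these genes are long: corrected for gene length, the medians of glutamate and GABA receptors shrank to -0.07 and -0.09, while that of monoamine receptors was -0.59, or -0.17 with subclasses weighted alike. Late activity genes had a median of 0.36, with 10 of 13 higher (percentile 99.9), among them the growth factor gene Bdnf, at 191 against 118 CPM, and the secreted peptide precursor gene Vgf, at 201 against 143. Heat shock genes had 0.28, with 11 of 11 higher (percentile 97.6), and ribosomal proteins 0.29, with 19 of 28 higher (percentile 99.8). The same medians were 0.07 and 0.08 once corrected for length. Neuropeptides had 0.49, with 5 of 9 higher (percentile 99.99): Cck was at 3074 against 1645 CPM, Adcyap1 at 68.5 against 31.2, and Sst, an interneuron peptide, at 13.5 against 25.8, but the median was -0.11 with no filter on low CPM. Mitochondrially encoded genes, which stand outside the nuclear total, had a median of -0.32, with 13 of 13 lower.

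The steroid list gave no clear direction in this pair. Steroid receptors and steroid metabolism had a median of -0.10, with 9 of 15 lower (percentile 11.9), and 0.0072 with subclasses weighted alike. The estrogen receptor gene Esr1 stood at 5.74 CPM in estrus, 6.98 in diestrus and 7.15 in male, and the progesterone receptor gene Pgr at 33.3, 39.0 and 38.9. The mineralocorticoid receptor gene Nr3c2 was at 33.6, 65.5 and 57.0 CPM, and Pgrmc1, a membrane progesterone-binding protein gene, at 411, 304 and 274. Estrogen responsive genes had -0.10, with 6 of 11 lower, and 0.13 with subclasses weighted alike. Calcium channels (-0.11, 12 of 18 lower, percentile 6.70) and potassium and HCN channels (-0.12, 17 of 23 lower, percentile 7.81) turned to 0.08 and 0.04 once corrected for length. Sodium channels had -0.16 (6 of 8 lower) and peptide and hormone receptors -0.14 (9 of 16 lower, percentile 4.42). Synapse scaffolds were at -0.05 and turned to 0.0019 with DESeq2 factors. Immediate early genes were at -0.08 (percentile 15.6), glucocorticoid responsive genes at 0.05, and clock genes at 0.13, or -0.02 with subclasses weighted alike. Cholesterol synthesis was at 0.20 (percentile 98.4) and nuclear oxidative phosphorylation at 0.12, which turned to -0.0072 once corrected for length.

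**Figure D2:**
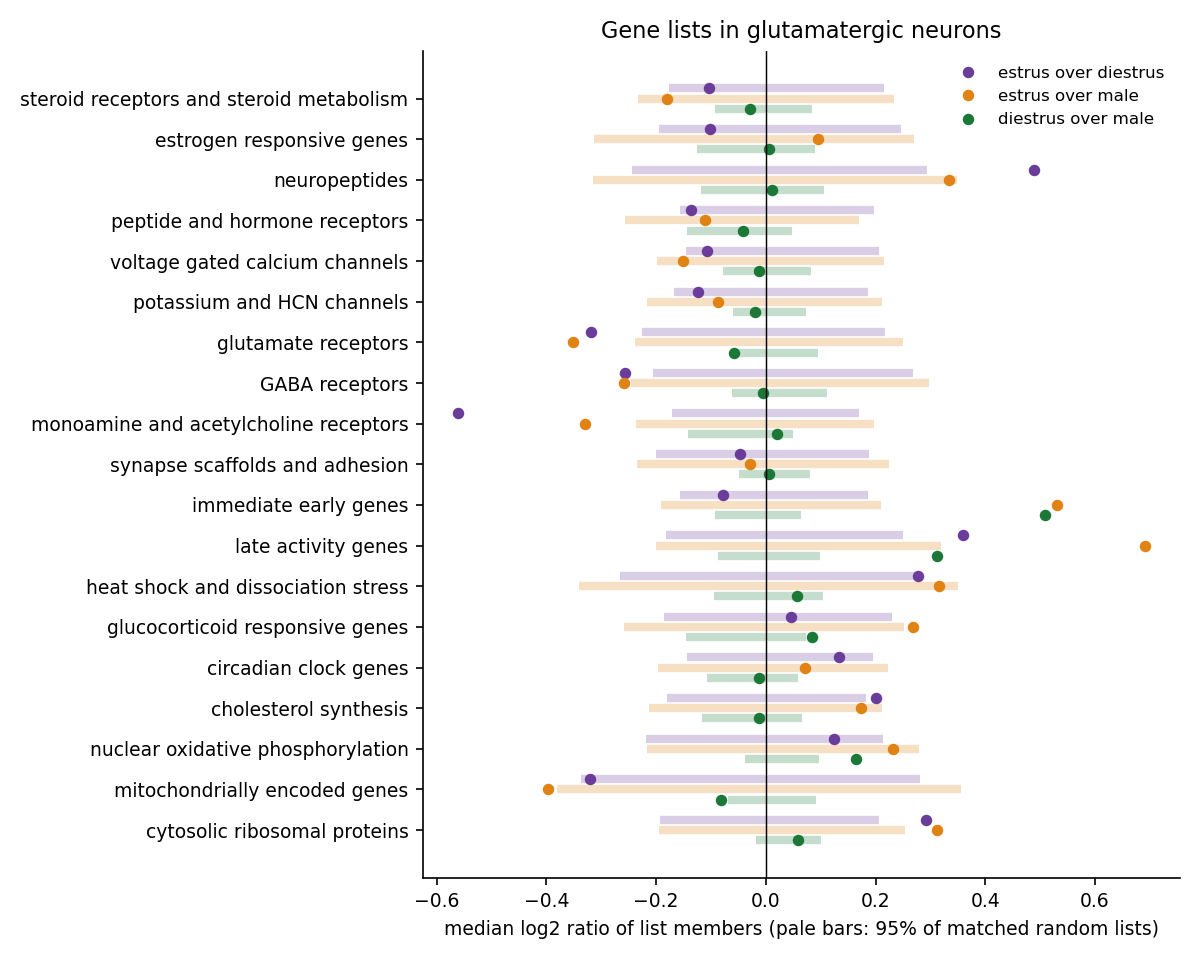
Median log2 ratio (horizontal axis) of each gene list with at least 8 measured members in every pair in glutamatergic neurons, for estrus over diestrus, estrus over male and diestrus over male, with points for the list medians and pale bars for the central 95% of 10000 matched random lists. Monoamine receptors lay at -0.56 for estrus over diestrus, and immediate early genes at 0.53 and 0.51 for estrus and diestrus over male.

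Long genes were lower in glutamatergic neurons of the estrus library than in those of either other library. Split by gene length into 5 groups of equal size, genes of glutamatergic neurons had median log2 ratios for estrus over diestrus of 0.27, 0.17, 0.03, -0.08 and -0.20, from the shortest group (median length 5.12 kb) to the longest (202 kb). Estrus over male gave 0.31, 0.18, 0.00, -0.12 and -0.26. Spearman's correlation of length and log2 ratio was -0.52 across 7329 genes and -0.55 across 7400 genes in these pairs, and -0.29 across 7360 genes for diestrus over male; genes are not independent replicates. For estrus over diestrus and over male the correlation was -0.58 and -0.55 in GABAergic neurons, -0.412 and -0.186 in oligodendrocytes, -0.324 and 0.027 in oligodendrocyte precursor cells, -0.249 and 0.101 in endothelial cells, -0.220 and 0.008 in astrocytes, -0.174 and 0.197 in microglia, -0.135 and 0.051 in pericytes, and 0.220 and 0.105 in border macrophages. Grm3 and Glra2 span 239630 and 198377 bases, against 2712 for Cdkn1c.

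**Figure D3:**
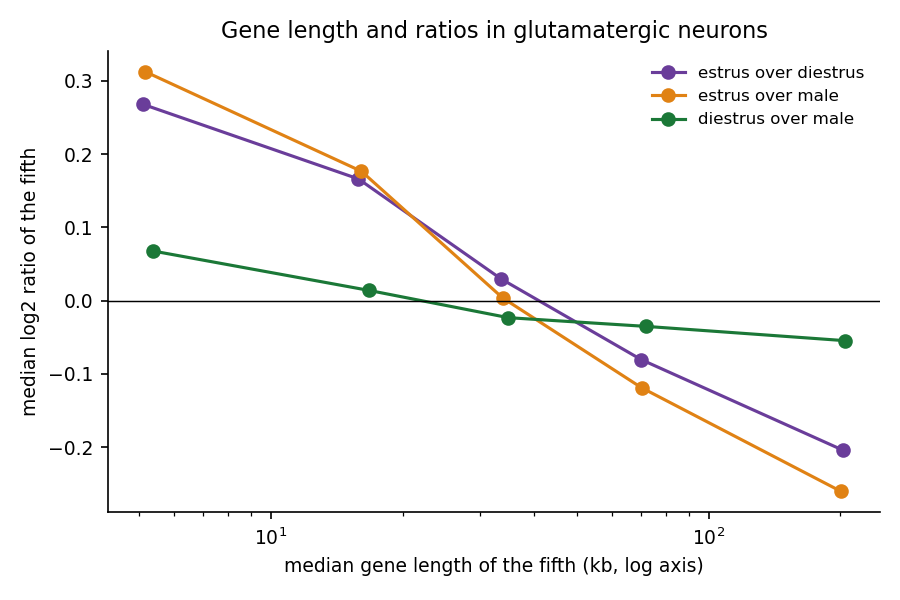
Median log2 ratio (vertical axis) of genes in 5 groups of equal size by gene length (horizontal axis, kb, log scale) in glutamatergic neurons, with 1 line per pair of libraries. For estrus over diestrus the points run from 0.27 in the shortest group to -0.20 in the longest.

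Against male, estrus glutamatergic neurons had more RNA of immediate early and late activity genes, which neuronal activity induces. Tissue was digested with papain, and whether these values reflect activity in the animal or the handling of the tissue was not tested. Immediate early genes had a median log2 ratio of 0.53, with 15 of 19 higher in estrus (percentile 100): Egr4 stood at 145 against 50.1 CPM and Fos, the classic activity marker, at 117 against 77.7, while Npas4 was lower at 18.2 against 30.5. Late activity genes had 0.69, with 11 of 13 higher (percentile 100), among them Bdnf, at 191 against 82.6 CPM, and Nrn1, a secreted synaptic factor gene, at 497 against 307. Corrected for length the medians of these lists were 0.32 and 0.52. Single genes highest over male included Ier5, an immediate early response gene (1: 155096361 to 155099636), at 173 against 55.4 CPM (log2 1.62, 1.56 to 1.72), its relative Ier5l (1.53, 1.45 to 1.67), and Pmepa1, an inhibitor of TGF-beta signalling (2: 173224458 to 173276533), at 160 against 51.0 CPM (1.64, 1.57 to 1.74). Cdkn1a, another inhibitor of cyclin-dependent kinases, had 1.60, and Hnrnpa0, Wnt4, Cdkn1c and Tnnc1 had 1.60, 1.66, 1.79 and 1.59. Gstp1 (1.84) and Hist1h4d (1.51) are uncertain here too. Hnrnpa0 lay above 1 in 9 of 9 classes, and Pmepa1 and Cdkn1a in 7.

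The genes lowest in estrus against male had log2 ratios from -1.56 to -1.31. Grm3 was lower by a log2 ratio of -1.38 (-1.43 to -1.34), and Oprm1, the mu opioid receptor gene (10: 6758506 to 7038198), by -1.32 (-1.47 to -1.25), at 21.4 against 55.0 CPM. Glra2 had -1.53, or -1.02 with subclasses weighted alike, and Slc8a3, a sodium and calcium exchanger gene, -1.31. Fndc9 (-1.54, or -1.01 without low-UMI subclusters) and Rpgrip1 (-1.51) were also lower, as were Thsd7b (-1.52), Nxph3 (-1.35) and Tle4 (-1.31), which shrank to -0.93, -0.60 and -0.73 with subclasses weighted alike. Nrg3os (-1.56) is antisense to Nrg3 and is uncertain without known strand use. Among the lists, glutamate receptors (-0.35, 18 of 19 lower, percentile 0.250), GABA receptors (-0.26, 10 of 13 lower) and monoamine receptors (-0.33, 12 of 16 lower, percentile 0.180) were lower. After correction for length they stood at -0.09, -0.02 and -0.39. Heat shock genes were at 0.32 (11 of 11 higher), ribosomal proteins at 0.31, nuclear oxidative phosphorylation at 0.23, glucocorticoid responsive genes at 0.27 (8 of 11 higher, percentile 98.2) and mitochondrially encoded genes at -0.40 (13 of 13 lower). Corrected for length, heat shock, ribosomal protein and oxidative phosphorylation genes shrank to 0.13, 0.11 and 0.16. Steroid receptors and metabolism were at -0.18, with 12 of 15 lower. Neuropeptides were at 0.33, which turned to -0.10 with no filter on low CPM. The median over all genes in this pair was -0.03, against 0.09 with edgeR TMM and 0.10 with DESeq2 factors, which turned potassium channels (-0.09), peptide receptors (-0.11) and synapse scaffolds (-0.03) above 0.

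Diestrus and male glutamatergic neurons were closer to each other, apart from immediate early and late activity genes, for which the same limit holds. Immediate early genes had a median log2 ratio of 0.51 for diestrus over male, with 17 of 18 higher in diestrus (percentile 100), and late activity genes 0.31, with 12 of 13 higher (percentile 100). Egr1, an immediate early transcription factor gene (18: 34859823 to 34864984), stood at 425 against 224 CPM (log2 0.92, 0.88 to 0.96), Egr3 at 142 against 88.3 (0.68), and Arc, which encodes a synaptic plasticity protein, at 75.0 against 42.8 (0.80, 0.72 to 0.90). Nptx2, a secreted pentraxin gene of excitatory synapses, had 0.80 (0.70 to 0.94), Ier5 0.82, Gadd45b 0.67, and Igfbp4, an insulin-like growth factor binding protein gene, 0.93 (0.83 to 1.10), or 0.60 with subclasses weighted alike. Myadm (0.82), Lpcat4 (0.79) and the X-linked Eif2s3x (0.71), which has a Y-linked paralog, were also higher in diestrus. Nuclear oxidative phosphorylation had 0.16, with 19 of 20 higher (percentile 100), although neurons of the male library were the shallowest.

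Lower in diestrus than in male were Cmss1 (-0.99), Fndc9 (-0.87), the adhesion molecule gene Nectin3 (-0.86), Rskr (-0.73), Thap3 (-0.67), Rad51ap2 (-0.67), Smoc2 (-0.66) and Zfp46 (-0.65), with the antisense genes Sorbs2os (-0.70) and Nrg3os (-0.64) uncertain. With subclasses weighted alike Nectin3, Rskr and Smoc2 shrank to -0.38, -0.36 and -0.29, and without low-UMI subclusters Fndc9, Sorbs2os and Nrg3os shrank to -0.44, -0.36 and -0.36. Under the same mean CPM over the 3 libraries, male stood highest against both female libraries in Fndc9, Nectin3, Sorbs2os, Zfp46 and Nrg3os, and lowest in Igfbp4, Ier5, Nptx2, Lpcat4 and Myadm. Receptor and channel lists lay near 0, at -0.06 for glutamate receptors, -0.0046 for GABA receptors, -0.01 for calcium channels and -0.03 for steroid receptors and metabolism, and each turned above 0 with edgeR TMM factors.

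GABAergic neurons, with 176, 304 and 340 cells, had the same direction for receptors and a higher level of peptide genes in estrus. Neuropeptides had a median log2 ratio of 0.36 over diestrus, with 15 of 16 higher (percentile 97.46), and 0.47 over male, with 13 of 16 higher (percentile 99.9), or 0.16 and 0.28 corrected for length. Sst stood at 9218, 4352 and 4993 CPM in estrus, diestrus and male, Npy at 5156, 3705 and 3659, and Crhbp, which binds corticotropin-releasing hormone, at 629, 255 and 312; all 3 lead a GABAergic cluster. Potassium and HCN channels had -0.32 over diestrus (20 of 23 lower, percentile 0.250) and -0.35 over male (22 of 23 lower, percentile 0.0400), with Kcnip4 at 1368, 3350 and 2777 CPM. Glutamate receptors had -0.43 and -0.42, GABA receptors -0.38 and -0.33, and monoamine receptors -0.33 and -0.38. Corrected for length, potassium and HCN channels were at -0.19 and -0.13, glutamate receptors at -0.08 and -0.12, GABA receptors at -0.10 and -0.11, and monoamine receptors at -0.22 and -0.28. Heat shock genes had 0.44 and 0.30, with 12 of 12 higher in both, or 0.26 and 0.16 corrected for length. Over diestrus, Eid2 (1.82, 1.62 to 2.06), the kinase gene Camk1d (1.65) and Cmss1 (2.46) were highest, with Gstp1 (1.84) and Hist1h4d (1.61), and the transcription factor gene Pbx3 (-2.04, -2.46 to -1.76), Htr1f (-1.67, -1.98 to -1.44), Slc44a5 (-1.47), Vwc2l (-1.46) and the phosphodiesterase gene Pde11a (-1.41) lowest. Over male, Rasl11a (2.02, 1.66 to 2.62), the C-type natriuretic peptide gene Nppc (1.85, 1.56 to 2.27), Cmss1 (1.91), Hist1h4d (1.83) and Yjefn3 (1.75, or 0.31 with subclasses weighted alike) were highest, and Epb41 (-1.46), the axon guidance gene Slit2 (-1.37), Htr1f (-1.36), Grip1os2 (-1.31) and the sodium channel gene Scn9a (-1.27) lowest. Yjefn3 is among the 10 leading genes of the Sncg-like subcluster. Sncg-like neurons, with 19 cells in estrus, were left out of that weighting. With cells thinned to 2000 UMIs, Rasl11a, Nppc and Slit2 shrank to 0.82, 1.09 and -0.38, and Pbx3 over diestrus had -1.29 with subclasses weighted alike. Camk1d lay above 1 in 8 of 9 classes over diestrus. It was highest in estrus and lowest in diestrus, at 802, 254 and 387 CPM in the 3 libraries, as were Cmss1 and Gm42418, a gene model known to collect reads from ribosomal RNA (9088, 2226 and 2940 CPM), so its ratio is uncertain.

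For diestrus over male in GABAergic neurons, Pbx3 (1.01, 0.78 to 1.28), Pde11a (0.99), the calcium channel subunit gene Cacna2d1 (0.96, 0.84 to 1.10), Rgs16 (0.89) and Nrp2 (0.87) were higher. Lower were the synaptotagmin gene Syt2 (-1.12, -1.64 to -0.74), Pvalb, the calcium-binding protein of fast-spiking interneurons (-1.06, -1.21 to -0.92), Eya4 (-0.91), Spon1 (-0.85) and Lynx1 (-0.81). With subclasses weighted alike Pde11a, Cacna2d1, Rgs16, Nrp2, Pvalb, Spon1 and Lynx1 were at 0.39, 0.37, 0.55, 0.44, -0.78, -0.46 and -0.52. With cells thinned Syt2, Pvalb, Eya4 and Nrp2 were at -0.06, -0.23, -0.44 and 0.43, so the lower Syt2 and Pvalb are not firm. Immediate early genes had a median of 0.19, with 15 of 18 higher (percentile 99.96), the same direction as in glutamatergic neurons.

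Microglia of the estrus library had more RNA of glucocorticoid responsive genes. Fkbp5, a co-chaperone of the glucocorticoid receptor (17: 28399094 to 28517527), stood at 842 CPM in estrus, 203 in diestrus and 153 in male, log2 ratios of 2.04 (1.99 to 2.12) and 2.45 (2.37 to 2.55). Ddit4, a stress-induced inhibitor of mTOR signalling (10: 59949669 to 59951834), was at 130, 19.1 and 15.0 CPM (2.71, 2.56 to 2.99, and 3.03, 2.83 to 3.42). Plaur, the urokinase receptor gene, had 2.30 and 2.52, and Ston1 2.07 over male. Microglial cluster 2 held 2351, 1011 and 704 cells in the 3 libraries, against 800, 1179 and 1105 in cluster 9. Glucocorticoid responsive genes had a median of 0.66 over diestrus and 0.78 over male, with 10 of 13 higher in each (percentile 100), or 0.33 and 0.34 with clusters weighted alike. Heat shock genes had 0.02 over diestrus, which turned to -0.04 with clusters weighted alike, and 0.09 over male. Cholesterol synthesis had -0.39 and -0.54, with 0 of 11 higher in both. Homeostatic genes were at -0.08 and -0.09, with P2ry12, a purinergic receptor gene, at 2108, 2380 and 2339 CPM; the median over all microglial genes went from -0.09 to 0.07 and from -0.07 to 0.11 with edgeR TMM factors, and the homeostatic list turned above 0 with it. Activation genes had 0.20 and 0.12, the second of which turned to -0.12 with clusters weighted alike, with Il1b, an inflammatory cytokine gene, lower at 14.4, 35.1 and 51.6 CPM. Immediate early genes had 0.38 and 0.42 but -0.16 and -0.23 with clusters weighted alike. Interferon response genes had -0.17 and -0.64, the second of which turned to 0.02 with cells thinned.

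The genes lowest in estrus microglia were mostly neuronal. Adamts16, a protease gene, had -2.77 over diestrus and -3.12 over male, while the neuronal genes Pcp4 (-2.38 and -2.42), Gng13 (-2.11 and -2.23), Eef1a2 (-2.06 and -2.15), Bc1 (-1.83 over diestrus) and Stmn2 (-2.01 over male) are read as background in this class, since free RNA in droplets puts neuronal UMIs into other cells. Synapse scaffolds behaved alike in microglia, with 0 of 19 higher in either pair and medians of -0.98 and -1.44. For diestrus over male, Nhs (1.08, 0.85 to 1.40), Zcwpw2 (0.85, or 0.52 with cells thinned), Atg4a (0.83), Zdhhc14 (0.82) and Myl4 (0.78) were higher, and Lars2 (-0.95), Cdk8 (-0.82), Cmss1 (-0.80), Chst1 (-0.71) and Fam122a (-0.66) lower. Lars2 was at 391, 212 and 410 CPM in the 3 libraries and, like Cmss1, lowest in diestrus along with Gm42418, so its ratio is uncertain. Myl4 is among the 10 leading genes of a glutamatergic cluster and is read as background too.

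Glucocorticoid responsive genes were higher in estrus in each of the other glial and vascular classes. In oligodendrocytes the median log2 ratio was 1.38 over diestrus and 1.67 over male, with 12 of 13 higher in both, and Sgk1, a kinase gene induced by corticosteroids, stood at 2194, 306 and 216 CPM. In astrocytes it was 1.28 and 0.95, with 11 of 13 higher, and Fkbp5 was at 111, 6.07 and 3.59 CPM. In endothelial cells it was 0.99 and 1.06, with Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at 790, 302 and 222 CPM. Pericytes had 1.06 and 1.37, but the endothelial gene Cldn5 ran alongside there, at 1257, 636 and 169 CPM, so RNA or cells of the endothelium can add to these values. Oligodendrocyte precursor cells had 0.84 and 0.77, and border macrophages 0.34 and 0.93. The percentile was 100 in each of these pairs except 97.6 for border macrophages over diestrus. For diestrus over male the medians lay between -0.01 in oligodendrocytes and 0.63 in border macrophages. Endothelial cluster 0, led among others by the list member Cdkn1a, held 2298, 44 and 6 cells, against 226, 1623 and 1330 in cluster 16 and 315, 426 and 305 in cluster 22; with clusters 16 and 22 weighted alike and cluster 0 left out, for want of 20 cells per library, the endothelial medians were 0.66 and 0.82. Most astrocytes lay in cluster 3 (1145, 669 and 1103 cells), most oligodendrocytes in clusters 13 (982, 943 and 1509) and 14 (602, 715 and 1429), and most pericytes in clusters 8 (97, 47 and 6) and 20 (344, 425 and 406). Myelin genes in oligodendrocytes lay near 0 at 0.05, 0.08 and 0.06 in the 3 pairs, with Mbp at 4253, 4100 and 3910 CPM. Endothelial barrier and transport genes in endothelial cells were at -0.10 and -0.02 in the estrus pairs and turned to 0.17 and 0.38 with edgeR TMM factors, which moved the median over all endothelial genes from -0.17 to 0.09 and from -0.22 to 0.17, and from -0.06 to 0.06 for diestrus over male. The same factors moved the all-gene median for estrus over male from -0.09 to 0.05 in oligodendrocytes, from -0.07 to 0.07 in astrocytes, from -0.14 to 0.07 in pericytes and from -0.18 to 0.06 in border macrophages. They moved it from -0.12 to 0.05 in pericytes for estrus over diestrus and from -0.16 to 0.05 in border macrophages for diestrus over male.

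**Figure D4:**
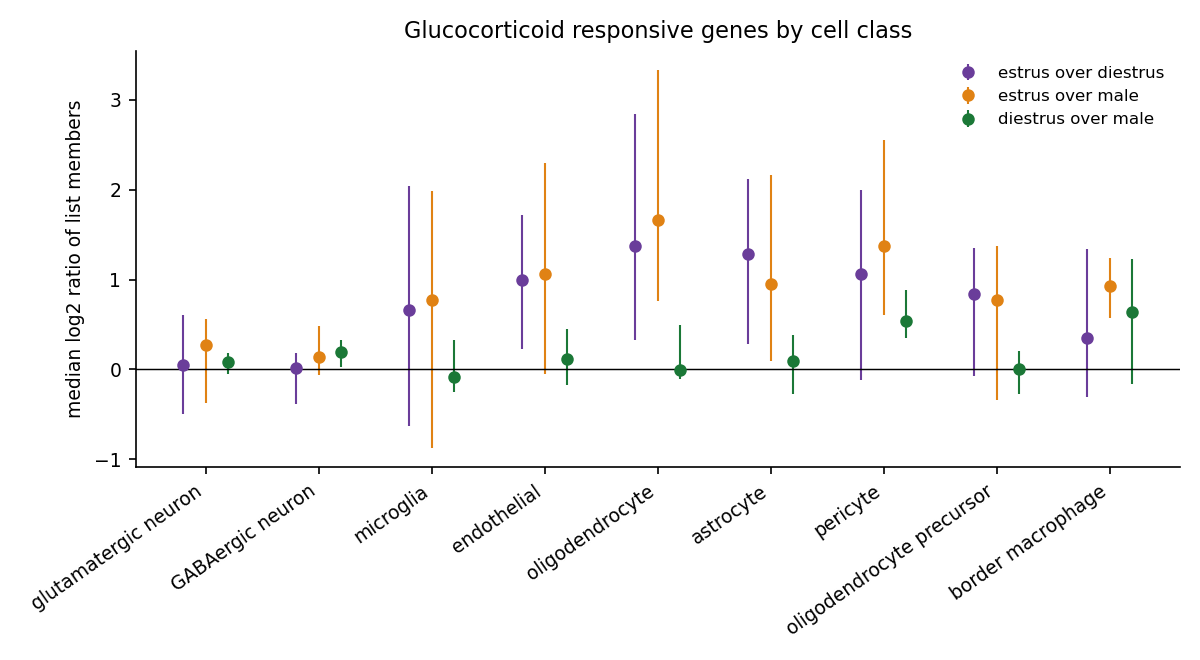
Median log2 ratio (vertical axis) of glucocorticoid responsive genes in 9 cell classes, with 1 point per pair of libraries and bars for the order-statistic interval over list members. Oligodendrocytes lay at 1.38 and 1.67 for estrus over diestrus and over male and at -0.01 for diestrus over male.

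Cacna1h, which encodes the T-type calcium channel Cav3.2, was a gene of interest fixed in advance. It lies on chromosome 17 at 25374285 to 25433783, on the minus strand, and spans 59499 bases. In glutamatergic neurons it had 603, 522 and 248 UMIs, or 11.7, 10.8 and 8.61 CPM in estrus, diestrus and male. The log2 ratio was 0.10 (-0.06 to 0.28) for estrus over diestrus, which counting error covers, 0.40 (0.23 to 0.66) for estrus over male and 0.30 (0.11 to 0.55) for diestrus over male. In GABAergic neurons it was at 8.32, 8.09 and 7.09 CPM, with 36, 42 and 34 UMIs, and all intervals held 0. After thinning to 2000 UMIs, 2.35% (1.61 to 3.30) of estrus, 2.38% (1.71 to 3.21) of diestrus and 2.10% (1.47 to 2.89) of male glutamatergic neurons held a UMI, against 29.0%, 20.8% and 11.6% without thinning; 1, 14 and 31 shallower neurons were left out. GABAergic neurons gave 3.43% (1.27 to 7.31), 2.34% (0.946 to 4.76) and 3.08% (1.49 to 5.59). Microglia, with medians of 5344, 4606.5 and 3625 UMIs, gave a background of 0.161%, 0.0470% and 0.293%. Among glutamatergic subclasses the highest shares stood in L5 ET-like neurons, at 13.8% (7.34 to 22.9), 6.11% (2.67 to 11.7) and 10.3% (5.06 to 18.1), with intervals that overlap, against 87.4%, 72.0% and 40.8% without thinning. No order of the libraries is read from these shares, since they and the CPM values order the libraries differently.

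**Figure D5:**
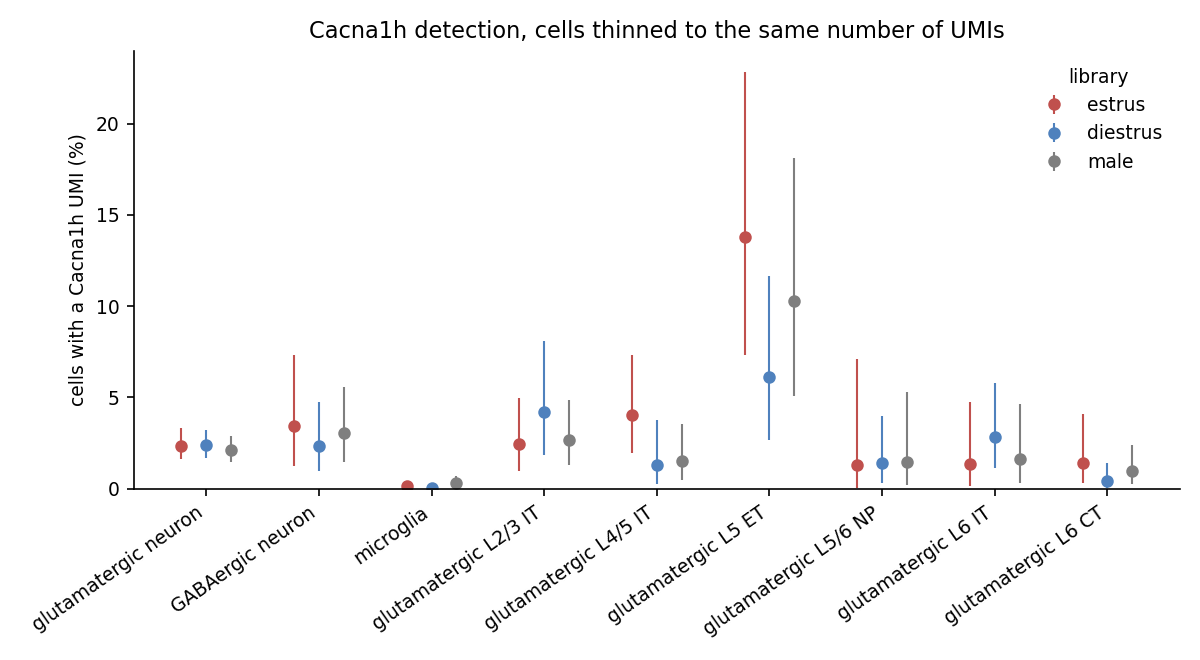
Share of cells with a Cacna1h UMI (percent, vertical axis) after thinning to 2000 UMIs in glutamatergic neurons, GABAergic neurons, microglia and 6 glutamatergic subclasses, with 1 point per library and Clopper-Pearson 95% intervals. L5 ET-like neurons lay at 13.8%, 6.11% and 10.3% in estrus, diestrus and male, and microglia at 0.161%, 0.0470% and 0.293%.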

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

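No test in this part was chosen after a result was seen, since none was run. The values below are cell counts of named clusters that entered none of the comparisons. Each cluster is listed because the Clopper-Pearson interval of its highest share among the libraries lay wholly above that of its lowest. Ependymal-like cells, which line the ventricles, were seen only in the diestrus library among the 3, with 93 cells (0.657%) against 0 in estrus and male, which allows shares of up to 0.0244% and 0.0194%. Neuroblast-like cells numbered 138 in diestrus (0.976%) and 132 in male (0.852%) but 4 in estrus (0.0325%). Vascular leptomeningeal-like cells, fibroblast-like cells of the vessel wall and meninges, numbered 159 in diestrus (1.12%), 98 in male (0.633%) and 32 in estrus (0.260%). Smooth muscle-like cells of vessels numbered 255 in diestrus (1.80%), 217 in estrus (1.77%) and 79 in male (0.510%). T cell-like cells numbered 40 in estrus (0.325%), 18 in diestrus (0.127%) and 25 in male (0.161%). Outside that rule, B cell-like cells numbered 28, 15 and 35 in estrus, diestrus and male, and committed oligodendrocyte precursor-like cells 54, 77 and 61.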

How the results depend on the processing

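Of the alternatives tried, mixed neuron subclusters kept, low-UMI neuron subclusters left out, clusters weighted alike and correction for gene length were chosen after seeing the data. With 1 library per group no replicate could be left out. No paired analysis was possible because the result comes from no test and each group has 1 library. Counted over results and alternatives, 108 of 215 class shares, 201 of 281 subclass shares, 1303 of 1788 gene ratios, 4048 of 4261 list medians and 117 of 176 Cacna1h shares stayed within their main interval. The others lay outside it, among them 19 list medians that had the other sign and whose main interval left out 0. The cause was not tested for any of the values below unless stated. Depth limits Cacna1h, with 36, 42 and 34 UMIs in GABAergic neurons.

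Class shares of glutamatergic neurons (main values 11.1%, 12.3% and 11.3% in estrus, diestrus and male) moved as follows. A minimum of 1000 genes gave 15.9% in diestrus and 14.9% in male, and one of 200 genes 10.9% and 9.93%. A mitochondrial maximum of 5% gave 10.4%, 9.85% and 6.84%. Keeping doublets gave 10.5% in estrus, clustering each library on its own 9.35% in estrus and 11.6% in diestrus, and resolution 0.5 gave 11.6% in diestrus and 10.0% in male. Keeping mixed subclusters gave 12.8%, 14.2% and 16.2%.

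Microglial shares (25.6%, 15.5% and 11.7%) were 27.1%, 20.5% and 16.0% with a minimum of 1000 genes and 31.0%, 21.0% and 19.0% with a mitochondrial maximum of 5%. They were 26.6%, 17.3% and 15.7% at resolution 0.5, 26.4%, 17.2% and 15.6% at resolution 2, and 26.5%, 16.7% and 15.7% with each library clustered on its own. Keeping doublets gave 17.0% in diestrus and 15.2% in male, and a minimum of 200 genes 14.1% in male.

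Among neurons, L2/3 IT-like shares (18.5%, 9.44% and 18.0%) were 22.9%, 10.8% and 20.0% at resolution 2 and 16.1%, 8.17% and 12.8% with mixed subclusters kept. They were 6.77% in diestrus and 12.4% in male with a mitochondrial maximum of 5%, 20.6% in male at resolution 0.5, and 27.6% in estrus with each library clustered on its own. L6 CT-like shares (13.7%, 24.7% and 20.7%) were 11.8%, 19.5% and 15.3% with the mitochondrial maximum of 5% and 11.9%, 21.3% and 14.8% with mixed subclusters kept. A minimum of 200 genes gave 20.5% in diestrus and 18.8% in male, resolution 0.5 gave 20.6% and 13.2%, and each library on its own gave 16.1% in estrus and 22.3% in diestrus.

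The Cacna1h share in glutamatergic neurons was 4.89%, 5.34% and 3.22% when cells were thinned to 4000 UMIs, 1.27% in diestrus and 0.973% in male at 1000 UMIs, and 29.0%, 20.8% and 11.6% unthinned, since more UMIs per cell give more cells with one. GABAergic neurons gave 0.568% in estrus and 1.18% in male at 1000 UMIs, and 15.3%, 11.2% and 8.82% unthinned. The Cacna1h log2 ratio for estrus over male in glutamatergic neurons was 0.22 with 10 CPM added, which shrinks low genes by construction. Over all barcodes, Xist was at 608 CPM in diestrus and Eif2s3y at 94.4 CPM in male.

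The list medians with the other sign are given next, with steroid receptors and metabolism, whose main interval included 0. With edgeR TMM and DESeq2 factors, steroid receptors and metabolism in glutamatergic neurons, diestrus over male, were at 0.046 and 0.044, mitochondrially encoded genes there at 0.005 and 0.0024, and endothelial oxidative phosphorylation, estrus over diestrus, at 0.137 and 0.148. Mitochondrially encoded genes there were also at 0.057 with the mitochondrial maximum of 5% and at 0.033 without low-UMI subclusters. That maximum gave 0.211 and 0.087 for ribosomal proteins and reactive genes in astrocytes, estrus over diestrus, and -0.082 for ribosomal proteins in pericytes, diestrus over male, which had -0.022 with clusters weighted alike. Under that weighting microglial immediate early genes, estrus over male, were at -0.228. Correction for gene length gave 0.035 for potassium and HCN channels in glutamatergic neurons, estrus over diestrus, and 0.045 and 0.028 for calcium channels and synapse scaffolds in GABAergic neurons, estrus over male. It gave 0.0043 and 0.0028 for ribosomal proteins in endothelial cells and astrocytes, diestrus over male. In GABAergic neurons, interferon response genes, estrus over diestrus, were at -0.766 with cells thinned and -0.084 with subclasses weighted alike, and astrocyte reactive genes, diestrus over male, at 0.103 with cells thinned.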

Other observations

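The tests of free RNA from 1 source, dissociation stress, time of day, cell states among microglia and endothelial cells, ribosomal RNA reads and cycle stage in this part were chosen only after the result was seen, and the 3 patterns weighed here were picked after 27 lists in 9 classes and 3 pairs had been looked over. Astrocytes of the estrus library had more RNA of the cholesterol synthesis pathway, whose product astrocytes supply to neurons. Its median log2 ratio was 0.57 over diestrus, with 14 of 15 members higher (percentile 100), and 0.39 over male, with 13 of 15 higher (percentile 99.99), against -0.15 for diestrus over male. Cyp51, a sterol demethylase gene, stood at 319 CPM in estrus, 185 in diestrus and 231 in male, and the squalene epoxidase gene Sqle at 184, 115 and 138. Reactive astrocyte genes were lower in estrus, with medians of -1.38 over diestrus (0 of 5 higher) and -0.97 over male: Gfap, the intermediate filament gene, was at 30.1, 130 and 70.1 CPM and the complement gene C4b at 10.4, 39.0 and 22.8. Gfap leads astrocyte cluster 28, which held 128 of 1393 estrus, 208 of 1042 diestrus and 453 of 1861 male astrocytes. With a mitochondrial maximum of 5% the first of these medians was 0.09, so it depends on that limit, and the cause was not tested. Immediate early genes in astrocytes were at -0.74 and -0.58, opposite in sign to estrus over male in glutamatergic neurons.

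Endothelial cells of the diestrus library had more RNA of interferon response and immediate early genes. Interferon response genes had a median log2 ratio of -0.45 for estrus over diestrus, with 10 of 12 members lower (percentile 0.130), and 0.31 for diestrus over male, with 11 of 12 higher (percentile 99.9). The antiviral genes Rsad2 and Ifit1 stood at 38.0, 88.8 and 77.9 CPM and at 105, 158 and 82.3 CPM in estrus, diestrus and male, while Isg15, a ubiquitin-like modifier gene, was highest in estrus at 209, 174 and 147 CPM. Immediate early genes had -0.79 and 0.47 in the same pairs, with Egr1 at 32.9, 229 and 145 CPM and Fos at 211, 460 and 291 CPM. Egr1, Egr3 and Arc were lower in estrus than in diestrus by a log2 ratio of at least 1 in 5, 4 and 6 classes. The immediate early part is thus not particular to endothelial cells. Different clusters held most endothelial cells of estrus and of the other libraries, as given above, and with clusters 16 and 22 weighted alike, without cluster 0, the estrus over diestrus medians were -0.28 and -0.80. In pericytes, interferon response genes had 1.45 for both female libraries over male, with 12 of 12 and 11 of 11 members higher, but Cldn5, an endothelial tight junction gene, ran alongside at 1257, 636 and 169 CPM.

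The first pattern was the higher level of glucocorticoid responsive genes in glia and vascular cells of the estrus library. Free RNA from 1 source is argued against as the whole cause, since the ratio between the CPM differences of 2 list members varied by a median of 55.2 times among 5 classes, over 28 pairs of members. General dissociation stress, at a heat shock median of 0.23 log2 units over those classes, is argued against as well. Under equal weights for clusters the list was still at a median of 0.90 over the 5 classes. That argues against cell states as the whole cause in astrocytes and oligodendrocytes at most. Pericytes entered that median with cluster 20 alone, since cluster 8 held only 6 male cells, so cell states were not tested there. Cell states stay open in microglia, where the list was at 0.331, below the bound of 0.5, and in endothelial cells, where cluster 0, with 80.9% of the estrus cells, was left out of that weighting. Free RNA in the droplets was not decided, since 50% of 54 pairs of member and class exceeded what the low-UMI barcodes of the estrus library held. A candidate explanation is time of day at collection: clock output genes stood above clock activators in estrus by a median of 1.06 log2 units over 5 glial and vascular classes, in the estrus pair with the lower median, with values from 0.34 in microglia to 1.45 in endothelial cells, both over male, and 2 or 3 activator genes per class, with Per2 at 20.6, 5.93 and 4.01 CPM and Arntl at 5.17, 16.3 and 18.5 CPM in endothelial cells, although Per2 itself responds to glucocorticoids and collection times were not analysed here; cycle stage, with 1 library per stage, and an acute hormone response stay open and untested.

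The second pattern was the lower level of long genes in glutamatergic neurons of the estrus library. Shares of the named neuron subclasses and low-UMI neurons are each argued against as the whole cause. Spearman's correlation of gene length and log2 ratio, taken as the value nearer to 0 of the estrus pairs, stayed negative. It was -0.502 with subclasses weighted alike, -0.514 without low-UMI neuron subclusters and -0.401 with cells thinned. Thinning changes the weight of each cell but not its expected profile, so the last value cannot decide on UMIs per cell. No biological explanation was tested, and the share of intronic reads or of nuclear RNA in each library was not analysed here. Some receptor and channel lists hold many long genes, so their lower medians in estrus over diestrus may belong to this pattern: once corrected for length, potassium and HCN channels turned from -0.12 to 0.035 and glutamate receptors from -0.32 to -0.07, but monoamine and acetylcholine receptors did not shrink, from -0.56 to -0.59, although they were at -0.17 with subclasses weighted alike.

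The third pattern was Cmss1, which was higher in estrus in each of the 9 classes. It ran alongside Gm42418, a gene model known to collect reads from ribosomal RNA: the ratio of Cmss1 to Gm42418 varied among the 9 classes by 1.40 times in estrus, 1.60 times in diestrus and 1.40 times in male, while Cmss1 itself varied by 6.18, 5.33 and 4.83 times. Ribosomal RNA reads are a candidate explanation that was not decided, since the ratio in diestrus passed the limit of 1.5 times set for it. The ratio was also higher in estrus, at 16.6% to 23.1%, than in diestrus, at 9.03% to 14.5%. Cycle stage, with 1 library per stage, stays open and untested.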
